A study of Mus musculus with 32 samples.

How the data were processed

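RNA was measured by sequencing in 32 libraries of mouse B cells, 16 from the CH12F3 line and 16 from spleen. Per the labels' protocols, total RNA was extracted with a Tiangen kit, ribosomal RNA was depleted, and strand-specific libraries were made with NEB kits, so spliced, unspliced and non-polyadenylated RNA can all enter the counts. Per the labels, polyadenylated RNA of Drosophila S2 cells was added in a fixed amount per cell, as a reference for the amount of RNA per cell. A library named by its group is ELOF1-proficient or ELOF1-deficient as its genotype label says.

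The deposited values are raw read counts per gene, 1 table per cell system with 1 column per library. Bowtie2, featureCounts and the builds mm10 and dm6 are named in the submitters' processing notes, without versions. The gene release, the use of strand and the treatment of reads that map to several places are not given in the sources used here, so overlapping genes, antisense partners and near-identical copies such as histone genes are uncertain. Per the file headers, the gene coordinates are those of the featureCounts table, with fly chromosomes marked as dm6. Each table held 60854 genes, of which 43345 were mouse and 17509 fly. A symbol was found for 42461 mouse genes by identifier, and 884 had none. Of the mouse genes, 33496 had the same start and end in the reference annotation of the same build used for names. No column of either table belonged to a sample outside the series.

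Mouse and fly counts were separated before anything else was computed, and the fly genes entered no library size of the main analysis. Mouse totals were 7112130 to 16359477 counts per library, and fly counts were 2.15% to 8.39% of the mouse counts. Genes without a symbol held 0.355% to 0.470% of mouse counts. With these totals, the median count of a tested gene was 173 to 348 in CH12F3 libraries and 227 to 354 in spleen libraries. Library names in the labels fall into 2 runs of numbers, 15 to 22 (8 libraries, the first library series) and 208 to 231 (24 libraries, the second). Both genotypes were present in both runs at CH12F3 day 1.5 and spleen day 2.5, and all other groups lay in the second run. Libraries of the first run had more mitochondrial ribosomal RNA, and 5467 of 14201 CH12F3 genes and 5389 of 13367 spleen genes differed between the runs at an edgeR adjusted p below 0.05.

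Genes were tested with the quasi-likelihood test of edgeR 4.0.16 (limma 3.58.1, R 4.3.3) on the deposited counts, with TMM scaling, the default filterByExpr filter (a minimum count of 10), and 1 fit per cell system over all 16 libraries with a term for each group and for the library series. This left 14201 CH12F3 and 13367 spleen genes, which held 99.9% of mouse counts in each system. Benjamini-Hochberg adjusted p below 0.05 was the threshold, adjusted p-values without another name are from this test, and fold changes are given as log2 with the standard error (SE). Where a count at an unadjusted p under 0.05 is given, chance alone gives about 1 in 20 of the genes tested. A count below that share shows no excess of small p-values. Expression is in CPM, counts scaled to a common library total, after TMM scaling, as mean ± SD over the libraries of a group. In 29 gene lists written before the data were examined, members were counted by the same test, once adjusted over all genes and once adjusted over the list alone. Lists were also compared with all other genes by camera with its preset correlation of 0.01, by camera with an estimated correlation, and tested by fry, with Benjamini-Hochberg adjustment over the lists with at least 5 tested genes. Where other splits of the libraries were fitted, camera with the preset correlation called a median of 7 to 10 lists in them, so its p-values alone carry little weight.

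Another 3 values were taken per library and compared by exact 2-sided permutation tests. They were the median log2 CPM of genes spanning 100 kb or more minus that of genes under 10 kb, the log2 ratio of the switched isotype to Ighm counts (Igha in CH12F3, Ighg1 in spleen), and the log2 ratio of fly to mouse counts. These made a family of 15 tests. Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 was used for these and for the plots.

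The genes named were chosen by a rule fixed before the data were examined. For each genotype comparison it took Elof1, Ung, Supt5, Trp53bp1, Ighm and Igha or, in spleen, Ighm, Ighg1 and Ighe. It added the 8 largest rises and 8 largest falls among genes past the threshold with a mean log2 CPM of at least 1 and non-overlapping groups, without predicted genes and immunoglobulin V, D or J segments, and up to 4 called members per list. For each time comparison it took 5 rises, 5 falls and up to 3 members per list, for each difference of effects the 5 smallest adjusted p-values, and up to 10 genes called in the same direction in both systems. Any other gene named was chosen after its values were seen, which is said beside it. Some genes that the rule names are not reported here.

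On counts simulated from the CH12F3 day 1.5 libraries with 14201 genes, 56% of genes changed 2-fold and 31% of those changed 1.5-fold were recovered. The shares were 39% and 6% at CH12F3 day 3 and 42% and 14% at CH12F3 day 7. In spleen cells, with 13367 genes, they were 74% and 42% at day 2.5 and 54% and 19% at day 3.5. Between 2 and 7 of the genes left unchanged in a simulation were called. The counts were drawn independently for each gene and library, without the pairs or other structure of the real libraries. Real error rates can therefore be higher: other splits of the spleen day 2.5 libraries called up to 1208 genes.

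The labels number the replicates but do not say whether a number marks a culture, clone, mouse or repeat preparation, so p-values measure the spread between these libraries, which may be technical. In CH12F3 cells, same-numbered vector and ELOF1 libraries deviated together. The correlations of their deviations from group and library series means across genes were 0.43 and 0.48 at day 1.5, 0.50 at day 3 and 0.34 at day 7, so the numbers were treated as pairs and the value of a fit with the replicate number as a block is given where it moved a count by over 1.5 times. In spleen cells, deviations from the group means correlated by 0.28 to 0.80 at day 2.5, which included the difference between library series. Beyond the series, replicates 1 to 3 gave 0.13, -0.20 and -0.12 at day 2.5 and 0.07, -0.28 and -0.12 at day 3.5. Counts of Xist and Ddx3y placed 4 of the 16 spleen libraries in male mice, replicate 2 of the wild type and replicate 3 of the knockout at both days. For replicates 2 and 3, same-numbered wild-type and knockout libraries therefore came from mice of different sex. Within a genotype, the deviations of same-numbered spleen libraries of days 2.5 and 3.5 correlated across genes by 0.17 to 0.19 in WT cells, against -0.17 to 0.00 for other pairs, so the numbers were treated as pairs across the days there, and by -0.03 to 0.22 against -0.23 to 0.13 in cKO cells.

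The alternatives tried, planned before the data were examined, were the size factors of DESeq2, scaling by fly counts, no filter, no series term, robust dispersions, the replicate block, a fit of the compared groups alone, each library series alone, each library left out in turn, and the Wald test of DESeq2 1.42.0. Runs without the libraries of male mice, the comparison of libraries across the spleen days, the replicate block for the differences in effect between CH12F3 days, gene lists within a library series, permutation within a library series and permutation of list means within same-numbered pairs were added after the data were seen.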

Results

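ELOF1 is an elongation factor that binds RNA polymerase II, and it has a part in the repair of damage that stalls the polymerase. The series is about damage caused by AID, the deaminase that starts class switch recombination in activated B cells, and its dependence on polymerase that carries ELOF1. The RNA libraries described here ask what the loss of ELOF1 does to the transcriptome of B cells that are switching their immunoglobulin isotype. They come from 2 mouse systems. The first is CH12F3, a B lymphoma line that switches from IgM to IgA when stimulated with an antibody to CD40, IL-4 and TGF-beta. Its Elof1 knockout carried either an empty vector (ELOF1-deficient, called vector) or an ELOF1 construct (ELOF1-proficient, called ELOF1), with 4 libraries of each at day 1.5, 2 of each at day 3 and 2 of each at day 7. The second is primary B cells from spleen, stimulated with IL-4 and LPS, which induce a switch to IgG1 and IgE. Here 5 libraries of conditional Elof1 knockout cells (cKO) and 5 of wild-type cells (WT) were made at day 2.5, and 3 of each at day 3.5. The depth was 7112130 to 15550229 mouse counts per library in CH12F3 cells and 9807560 to 16359477 in spleen cells. Fold changes between genotypes are ELOF1-deficient over ELOF1-proficient throughout.

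Elof1 itself (chromosome 9, 22112989 to 22117148, minus strand, mm10) was low in every deficient library. In CH12F3 cells at day 1.5 its counts were 11 to 54 in the 4 vector libraries and 2619 to 5956 in the 4 ELOF1 libraries, or 3.76 ± 1.99 against 467 ± 233 CPM (SD, n = 4 each), a 120-fold difference. Its counts were 17 and 21 against 3949 and 1981 at day 3, and it was at 2.14 ± 1.66 against 274 ± 164 CPM at day 7 (SD, n = 2 each). In spleen cells Elof1 was 4.20 ± 1.80 CPM in cKO and 29.0 ± 16.5 CPM in WT libraries at day 2.5 (SD, n = 5 each), and 5.87 ± 1.58 against 27.5 ± 11.3 CPM at day 3.5 (SD, n = 3 each). The fold differences there were 7.14 and 4.69. In each of the 5 comparisons every deficient library lay below every proficient library. The construct held Elof1 in CH12F3 cells at a level that varied between libraries, from 140 CPM in replicate 2 at day 3 to 681 CPM in replicate 1 at day 1.5.

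**Figure D1:**
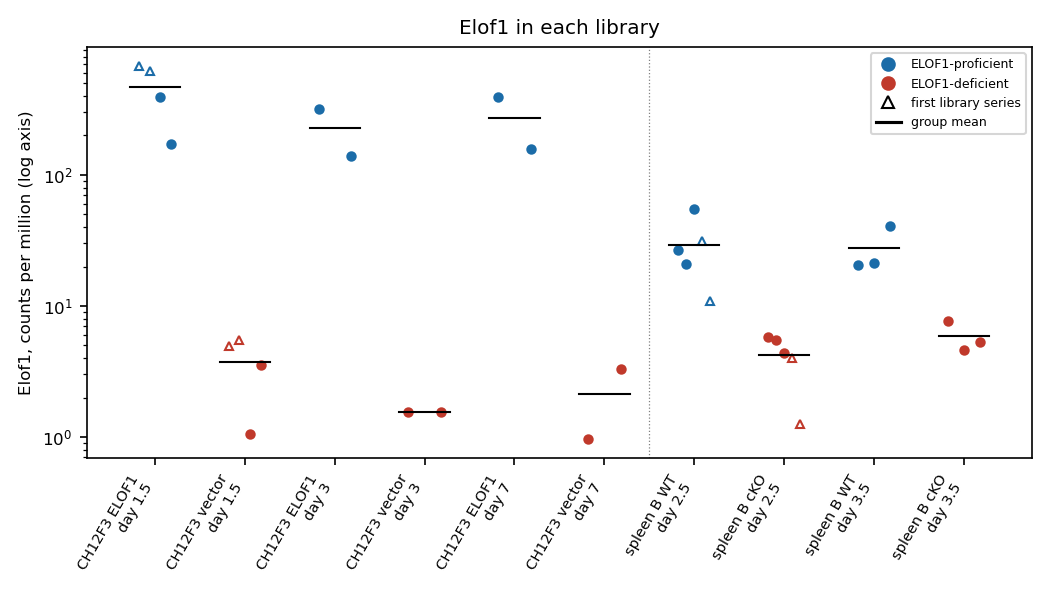
Elof1 in CPM, on a log axis, in each of the 32 libraries, by group, with lines at the group means and open triangles for the libraries of the first library series. Every ELOF1-deficient library lies below every ELOF1-proficient library of its cell system and day, and the ELOF1 construct gave 467 CPM on average at day 1.5 against 29.0 CPM in wild-type spleen cells at day 2.5.

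In CH12F3 cells at day 1.5 the genes that rose without ELOF1 included 5 of 31 tested genes of B cell activation and 4 of 16 of the response to IL-4. Stat5a, a transcription factor downstream of cytokine receptors, rose from 98.9 ± 15.6 to 195 ± 34.8 CPM (log2 fold change 0.97 ± 0.15, SE, adjusted p = 0.0078). Nfkb2, which encodes the precursor of the non-canonical NF-kB subunit, rose from 253 ± 13.6 to 364 ± 23.3 CPM (0.52 ± 0.06, adjusted p = 0.0022). The chemokine gene Ccl22 rose by 0.68 ± 0.12 to 4317 ± 1055 CPM, and Irf4, a transcription factor of activated B cells, by 0.50 ± 0.10. The germline transcripts and isotype genes Ighe and Ighg1, which IL-4 induces, were 3.02-fold and 2.90-fold higher, at the low levels of 9.74 ± 4.45 and 15.5 ± 2.14 CPM. In all, 164 of 14201 genes changed, 86 higher and 78 lower, 53 of them 2-fold or more.

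The genes with the largest changes were ranked among called genes with a mean log2 CPM of at least 1 and no overlap of the groups, without predicted genes and immunoglobulin V, D or J segments. Of these, the largest rises were in Creb3l4, a membrane-anchored CREB-family transcription factor (1.96 ± 0.30, adjusted p = 0.0079), Nrgn, a calmodulin-binding protein (1.57 ± 0.29), Ighg1 (1.54 ± 0.24), the microRNA gene Mir7676-1 (1.41) and the taste receptor subunit Tas1r3 (1.12). They were followed by Srgn, a granule proteoglycan (1.05 ± 0.19, 196 ± 29.7 against 102 ± 46.5 CPM), Gpr183, the oxysterol receptor that guides B cell migration (1.01 ± 0.12, adjusted p = 0.0018), and the lysophospholipid receptor Gpr55 (1.01 ± 0.19). Besides Elof1 (-6.91 ± 0.47, adjusted p = 1.1e-05), the largest falls by this ranking were in Prdm1, the regulator of plasma cell differentiation (-2.87 ± 0.62, adjusted p = 0.043, 3.22 ± 1.63 against 27 ± 16.3 CPM), Serpinf1, a secreted serpin (-2.03 ± 0.46), and Mmp19, a matrix metalloproteinase (-1.79 ± 0.35). Csgalnact1, an enzyme of chondroitin sulfate synthesis (-1.67 ± 0.32), Zfyve28 (-1.61 ± 0.35), the smooth muscle actin gene Actg2 (-1.47 ± 0.27) and the matrix protein gene Fras1 (-1.44 ± 0.29, 59.4 ± 15.4 against 178 ± 86.8 CPM) also fell. Several of these were scarce, with Serpinf1 at 5.23 ± 2.60 against 22.8 ± 9.56 CPM and Actg2 at 1.49 ± 0.684 against 4.12 ± 1.80 CPM.

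By gene list, the IL-4 and activation genes stood out. Of 31 tested genes of the B cell activation list, 5 rose and none fell, and 20 rose and 0 fell when adjusted over the list alone. The median log2 fold change was 0.50, and the list was higher than other genes (camera adjusted p = 6.71e-21, adjusted p = 0.0339 with an estimated correlation). In other splits of these libraries camera with the preset correlation called a median of 9 lists, against 11 in the real split. Of 16 genes of the IL-4 and STAT6 list, 4 rose (Ighe, Il4ra, Stat6 and Ccl22) and none fell, or 9 and 1 adjusted over the list alone, with a median of 0.50 (camera adjusted p = 3.17e-09, adjusted p = 0.0339 with an estimated correlation). Il4ra, the receptor subunit, had a log2 fold change of 0.49 ± 0.10 and Stat6, its transcription factor, one of 0.48 ± 0.08. These medians were 0.42 and 0.41 when libraries were scaled by the fly RNA. All 24 cholesterol synthesis genes had positive fold changes, with a median of 0.40, or 0.25 with fly scaling, but none passed the test over all genes and 1 did over the list alone (camera adjusted p = 5.96e-11, adjusted p = 0.333 with an estimated correlation). The 26 immediate-early genes had a median of 0.24, or 0.11 with fly scaling, with 1 called (Nr4a1, 1.11 ± 0.23) and 7 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.000415, adjusted p = 0.333 with an estimated correlation). Of 23 known off-target loci of AID, Il4ra and Pim1 (0.40 ± 0.09) rose, and 10 were higher and 1 lower adjusted over the list alone. That list's median was 0.08, or -0.0021 with fly scaling, and its call (camera adjusted p = 0.00262) was lost at adjusted p = 0.333 with an estimated correlation.

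The genes of the switching machinery gave no call in CH12F3 cells at day 1.5 in the main fit. That fit leaves the pairs out of account, so a change that it missed is not excluded. The log2 fold change of Ung, the uracil glycosylase, was -0.11, and those of Supt5, an elongation factor that AID binds, and Trp53bp1, of end joining, were 0.03 and -0.04. None of 25 genes of AID and uracil processing and none of 27 genes of end joining and damage signalling passed edgeR's quasi-likelihood test, over all genes or over the list alone. In 41 polymerase II elongation factors the only call was Elof1, and of 25 genes of transcription-coupled repair none was called, with 1 lower adjusted over the list alone. The markers of T and NK cells, 9 genes at low counts, had a median of -0.73 (camera adjusted p = 0.00602, adjusted p = 0.333 with an estimated correlation), with no member called. With the replicate number as a block, 1221 genes changed at day 1.5, 639 higher and 582 lower. With libraries scaled by the fly RNA there were 45, of which 5 were higher and 40 lower. In the first and second library series alone there were 52 and 0 (902 at an unadjusted p under 0.05 in the second), and without the term for library series there were 22. There were 64 with only the compared groups in the fit, 735 without the filter and 447 by DESeq2. Leaving out 1 library gave 41 (vector replicate 2), 48 (ELOF1 replicate 1), 58 (vector replicate 1), 62 (ELOF1 replicate 2), 66 (ELOF1 replicate 3) and 98 (vector replicate 4) genes.

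**Figure D2:**
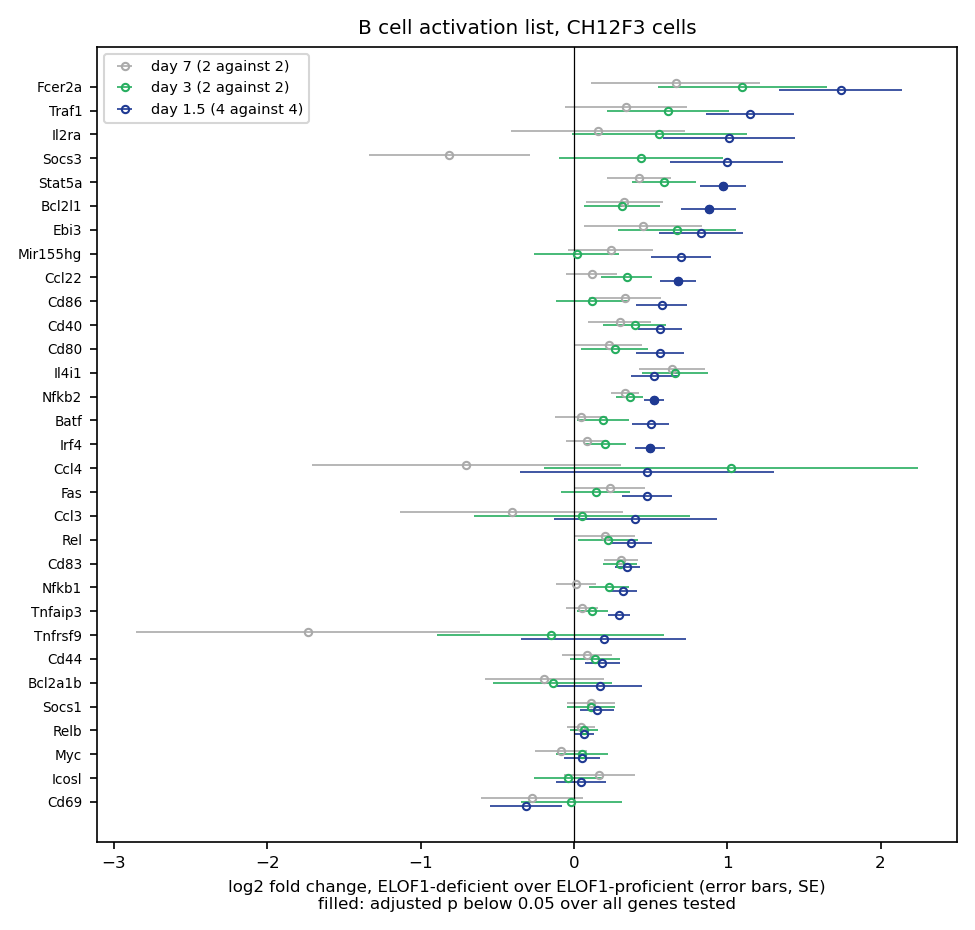
Log2 fold change, vector over ELOF1, of each of the 31 tested genes of the B cell activation list in CH12F3 cells at days 1.5, 3 and 7, with SE as error bars and filled points where the adjusted p over all genes was below 0.05. At day 1.5 the median was 0.50 and 5 genes were called, at day 3 it was 0.22 and at day 7 it was 0.16, both with none called. With fly scaling the medians were 0.42, 0.034 and 0.021.

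At day 3 of CH12F3 culture Elof1 was the only gene that passed the test (-7.19 ± 0.70, adjusted p = 0.0012, n = 2 each), with 590 genes at an unadjusted p under 0.05 and 13 by DESeq2. The IL-4 and STAT6 list had a median of 0.33 in its 16 genes, 3 of them higher and 1 lower adjusted over the list alone (camera adjusted p = 6.77e-07, adjusted p = 0.106 with an estimated correlation). That of B cell activation had a median of 0.22, with 1 of 31 genes higher adjusted over the list alone (camera adjusted p = 1.66e-07, adjusted p = 0.363 with an estimated correlation). With fly scaling these medians were 0.14 and 0.034. Igha, the isotype that CH12F3 cells switch to, had a log2 fold change of -0.56 ± 0.14 (adjusted p = 0.826). With the replicate number as a block 35 genes changed, and without the filter 48 did. With only the compared groups in the fit none did by edgeR (441 at an unadjusted p under 0.05). Leaving out either vector library ended the call of Elof1.

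At day 7, 5 genes passed the test in CH12F3 cells. Ighe was higher in vector cells (2.55 ± 0.34, adjusted p = 0.022, 9.98 ± 0.905 against 1.70 ± 0.252 CPM), as was Eno2, a glycolytic enolase (0.82 ± 0.12, adjusted p = 0.037, 102 ± 17 against 57.8 ± 4.55 CPM). Lower were Elof1 (-6.92 ± 0.67), Etl4 (-1.58 ± 0.24, 5.07 ± 1.08 against 15.3 ± 1.44 CPM) and Uqcc2, an assembly factor of respiratory complex III (-1.06 ± 0.16, adjusted p = 0.042, 18.9 ± 2.19 against 39.4 ± 1.95 CPM). Ighe and Eno2 had also risen at day 1.5, and Elof1, Etl4 and Uqcc2 had also fallen then. Igha was 1775 ± 138 CPM in vector and 3178 ± 25.7 CPM in ELOF1 libraries (-0.84 ± 0.14, adjusted p = 0.054), and Ighm was 1949 ± 493 against 1065 ± 877 CPM (0.87 ± 0.46, adjusted p = 0.912). The IL-4 and STAT6 list had a median of 0.29, with Ighe called and 2 of 16 genes higher adjusted over the list alone (camera adjusted p = 8.52e-06, adjusted p = 0.15 with an estimated correlation). With fly scaling this median was 0.16. A fit with the replicate number as a block gave 70 genes. With fly scaling or without the term for library series 1 gene was called, and with only the compared groups in the fit none was by edgeR (502 at an unadjusted p under 0.05). There were 8 with robust dispersions, 110 without the filter and 27 by DESeq2. Leaving out 1 library gave 0 (vector replicate 1), 1 (ELOF1 replicate 1) or 2 genes (either replicate 2).

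No gene passed a test of whether the genotype difference at day 3 or day 7 differed from that at day 1.5. By edgeR 173 and 272 of 14201 genes had an unadjusted p under 0.05, fewer than the 1 in 20 that chance gives, and DESeq2 called 0 in both. With the replicate number as a block edgeR also called 0, with 368 and 652 at an unadjusted p under 0.05. Among the smallest p-values of the main fit, without the block, were Cdhr5, Sec31b and Mucl3 for day 3 and Lncpint, Ighd and Slc2a3 for day 7, each with an adjusted p of 1. Of the 86 genes higher at day 1.5, 86 had a positive fold change at day 3 and 83 at day 7, and all 78 genes lower at day 1.5 had a negative one at both days. The comparisons of all 3 days come from 1 fit and share its estimate of spread and term for library series, so these counts are not independent evidence.

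In ELOF1-proficient CH12F3 cells the glycolysis genes were lower at day 3 than at day 1.5. None of the 27 passed the test over all genes, but 13 were lower and 0 higher adjusted over the list alone, with a median of -0.42 (camera adjusted p = 4.22e-17, adjusted p = 0.0214 with an estimated correlation). Pdk1, which restrains pyruvate oxidation, had a log2 fold change of -0.55 ± 0.12 and Pgk1, of the glycolytic chain, one of -0.66 ± 0.17, examples chosen after the values were seen. Of 26 immediate-early genes 8 were lower adjusted over the list alone, with a median of -0.35 (adjusted p = 0.0286 with an estimated correlation), and the 17 TGF-beta response genes had a median of -0.23, with 2 lower adjusted over the list alone (adjusted p = 0.0214 with an estimated correlation). The kinase gene Prkd2 (-0.82 ± 0.11, adjusted p = 0.034) was the only gene called, with 598 at an unadjusted p under 0.05. From day 1.5 to day 7 there were 7 calls, 4 higher and 3 lower. Igha, the isotype that CH12F3 cells switch to, rose from 1634 ± 241 to 3178 ± 25.7 CPM (0.80 ± 0.13, adjusted p = 0.043), the cytokine gene Il6 rose from 0.547 ± 0.484 to 8.07 ± 0.456 CPM (3.27 ± 0.44), and the kinase gene Rps6ka2 rose by 1.29 ± 0.20. The syndecan gene Sdc4 (-1.33 ± 0.17), Cntnap1 (-0.83 ± 0.11) and Tgif1, a repressor of TGF-beta responses (-0.60 ± 0.09), fell. The glycolysis median was -0.35 at day 7, with 12 genes lower adjusted over the list alone (camera adjusted p = 9.26e-14, adjusted p = 0.0587 with an estimated correlation). The call of Prkd2 was lost with fly scaling. At day 7 there were then 4 calls, 4 higher and 0 lower, of which 2 were among the 7. No gene was called at either day without the term for library series or in the second library series alone, while DESeq2 called 23 genes at day 3 and 101 at day 7. Without the filter there were 64 and 2.3e+02 (rounded). No fit paired libraries across the CH12F3 days, which the labels do not tie, so the counts and list calls of these steps leave such a pairing out of account. The second principal component set replicate 3 of day 1.5 with replicate 1 of days 3 and 7, and replicate 4 with replicate 2. Of the libraries that could be left out, ELOF1 day 1.5 replicate 2 alone kept the call at day 3, and at day 7 there were 0 calls without day 1.5 replicate 4 or either day 7 library and 4 without day 1.5 replicate 1 or 3.

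The isotype gene Ighg1 was lower in spleen B cells without ELOF1 at day 2.5. Ighg1 (chromosome 12, 113325240 to 113330523, minus strand, mm10) was 461 ± 73.9 CPM in cKO and 1263 ± 340 CPM in WT libraries (-1.43 ± 0.13, adjusted p = 2.8e-05, n = 5 each), and Ighg2b fell by 1.44 ± 0.28. Asns, asparagine synthetase (-0.94 ± 0.16, 33.4 ± 6.01 against 64.0 ± 11.6 CPM), and Ifih1, an RNA sensor (-0.63 ± 0.11), also fell. The homing receptor gene Ccr7 (1.12 ± 0.15, 55.1 ± 12.5 against 25.3 ± 6.58 CPM) and the egress receptor gene S1pr1 (0.85 ± 0.17) rose. In all, 693 of 13367 genes changed, 377 higher and 316 lower, 100 of them 2-fold or more.

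Among called genes without overlap of the groups, ranked as at CH12F3 day 1.5, the largest rises at day 2.5 were in Gramd2 (1.94 ± 0.26, adjusted p = 0.00043, 17.3 ± 8.75 against 4.30 ± 0.515 CPM), Tspoap1 (1.87 ± 0.31, 109 ± 50.1 against 30.6 ± 23.1 CPM), the E-cadherin gene Cdh1 (1.87 ± 0.38), and S100a6, a calcium-binding protein (1.74 ± 0.28). After them came Lynx1 (1.69 ± 0.15, adjusted p = 2e-05), the schlafen gene Slfn1 (1.69 ± 0.34), S100a4 (1.62 ± 0.38) and Tnp2, a sperm nuclear protein (1.57 ± 0.37). The largest falls by this ranking were in Elof1 (-2.84 ± 0.37), the ATP-gated channel gene P2rx3 (-1.96 ± 0.29), Ighg2b, Egr2, a transcription factor induced by the antigen receptor (-1.43 ± 0.17, 25.1 ± 3.34 against 67.8 ± 13.1 CPM), and Ighg1. They were followed by Ido2, of tryptophan breakdown (-1.35 ± 0.16), the semaphorin gene Sema6d (-1.31 ± 0.18) and Ifi213, of the interferon-inducible PYHIN family (-1.30 ± 0.35). Ung (-0.15), Supt5 (0.12), Trp53bp1 (-0.14), Ighm (0.29 ± 0.17) and Ighe (-0.56 ± 0.36) were not called.

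By list at day 2.5, 8 of 27 genes of the integrated stress response fell and 1 rose, or 15 and 1 adjusted over the list alone, with a median of -0.38 (camera adjusted p = 8.46e-08, adjusted p = 0.656 with an estimated correlation, fry adjusted p = 0.0400). Asns, Psph, of serine synthesis (24.4 ± 3.06 against 38.4 ± 5.35 CPM), and Pycr1, of proline synthesis (-0.68 ± 0.14), were among those that fell, and Atf5, a stress-induced transcription factor, was the member that rose (1.29 ± 0.17, 138 ± 36.1 against 58.2 ± 23 CPM). Of 35 interferon-stimulated genes 7 fell and 1 rose, with a median of -0.35 (camera adjusted p = 2.26e-06, adjusted p = 0.656 with an estimated correlation). Isg15 (-0.68 ± 0.15) and Ifi27l2a (48.1 ± 7.62 against 78.5 ± 21.6 CPM) fell, while the guanylate-binding protein gene Gbp2 rose (0.65 ± 0.09, 539 ± 31.5 against 344 ± 23.2 CPM). Of 34 genes of mature B cell identity 6 rose and 2 fell, or 12 and 3 adjusted over the list alone. Besides Ccr7 and S1pr1, the transcription factor genes Spib (385 ± 131 against 274 ± 88.3 CPM) and Klf2 (0.77 ± 0.21) rose, and Ebf1 (80.8 ± 13.7 against 115 ± 34 CPM) and the inhibitory receptor gene Btla fell (-0.74 ± 0.15, chosen after its value was seen). That list had a median of 0.09 (camera adjusted p = 0.00527, adjusted p = 0.656 with an estimated correlation), which was -0.06 with fly scaling.

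The B cell activation genes moved both ways in spleen cells at day 2.5. Of 29 tested, 3 rose and 6 fell, or 4 and 8 adjusted over the list alone, with a median of -0.06 (camera adjusted p = 0.235), which was -0.21 with fly scaling. The costimulatory genes Cd86 (0.66 ± 0.13, 109 ± 21 against 69.3 ± 22.7 CPM) and Cd40 (0.38 ± 0.07) and the amino acid oxidase gene Il4i1 (0.43 ± 0.09) rose. The adhesion receptor gene Cd44 (-0.49 ± 0.09), Irf4 (-0.47 ± 0.10, 239 ± 29.6 against 331 ± 55.9 CPM) and Ccl22 (-0.85 ± 0.19) fell. Of 24 plasma cell genes 3 fell (Zbtb20, -1.68 ± 0.32, Irf4 and Ighg1) and 0 rose, with a median of -0.17 (camera adjusted p = 4.67e-05, adjusted p = 0.656 with an estimated correlation), and of 11 immunoglobulin constant regions 2 fell, with a median of -0.56 (camera adjusted p = 0.000625, adjusted p = 0.656 with an estimated correlation). Of 24 known AID off-target loci 3 rose and 1 fell, and of 17 TGF-beta response genes 2 rose, the repressor Ski (0.52 ± 0.09) and Id2 (7.63 ± 2.48 against 4.35 ± 0.817 CPM). In DNA repair lists, Msh6, of mismatch repair, rose by 0.24 ± 0.06, and Rad18, a ubiquitin ligase of damage tolerance, and Shld2, of the shieldin complex, fell (38.8 ± 4.49 against 50.5 ± 9.18 and 9.46 ± 1.52 against 12.6 ± 2.06 CPM). Of the elongation factors, the kinase gene Cdk9 rose by 0.25 ± 0.07 and Elof1 fell. Among markers of other cells, the T cell kinase gene Lck (-0.54 ± 0.11) and the dendritic cell genes Zbtb46 (-0.94 ± 0.15) and Flt3 (-1.22 ± 0.30) fell, while the medians of the 9 T and NK cell markers and the 7 myeloid markers were 0.10 and 0.23, the former -0.09 with fly scaling.

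With the replicate number as a block 1543 genes changed in spleen cells at day 2.5, 837 higher and 706 lower. With fly scaling 93 changed, 30 higher and 63 lower. In the first library series alone, 2 against 2 libraries, none passed edgeR's test (195 at an unadjusted p under 0.05). There were 203 without the term for library series, 343 with only the compared groups in the fit, 173 without male mice, and 425, 448 and 450 without WT replicate 1, cKO replicate 2 and cKO replicate 3.

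**Figure D3:**
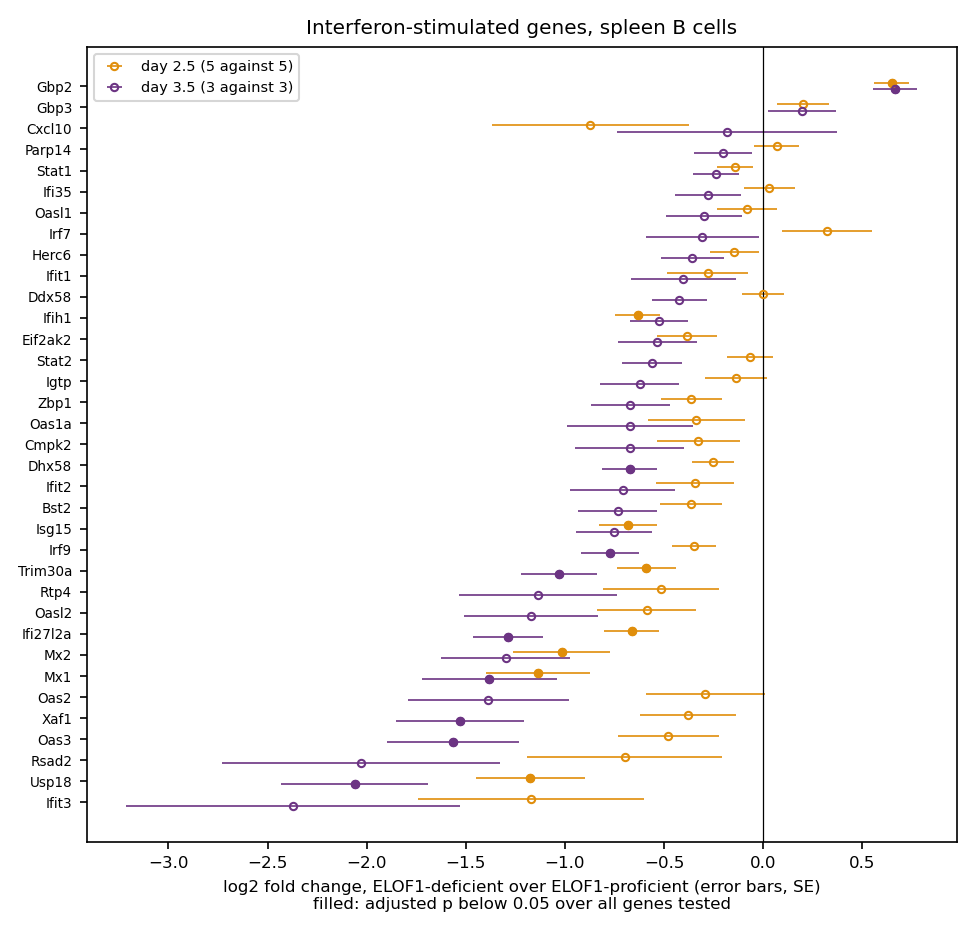
Log2 fold change, cKO over WT, of each of the 35 tested interferon-stimulated genes in spleen B cells at days 2.5 and 3.5, with SE as error bars and filled points where the adjusted p over all genes was below 0.05. The median was -0.35 at day 2.5 and -0.67 at day 3.5, and Gbp2 was higher in cKO cells at both days.

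At day 3.5 the interferon-stimulated genes of spleen B cells were lower without ELOF1. Of 35 tested, 8 fell and 1 rose, or 24 and 1 adjusted over the list alone, with a median of -0.67 (camera adjusted p = 6.4e-22, adjusted p = 0.104 with an estimated correlation, fry adjusted p = 0.0175). Usp18, which limits interferon signalling, was 2.72 ± 0.768 CPM in cKO and 11.4 ± 4.41 CPM in WT libraries (-2.06 ± 0.37, adjusted p = 0.0088, n = 3 each). Ifi27l2a was 44.3 ± 6 against 108 ± 8.85 CPM (-1.29 ± 0.18, adjusted p = 0.0014), and Trim30a 57.8 ± 7.65 against 118 ± 18.5 CPM (-1.03 ± 0.19), while Gbp2 rose again (0.67 ± 0.11). Of 27 genes of the integrated stress response 6 fell and 1 rose, or 17 and 1 adjusted over the list alone, with a median of -0.45 (camera adjusted p = 2.06e-15, adjusted p = 0.104 with an estimated correlation, fry adjusted p = 0.00749). Asns (-1.30 ± 0.21, 39.0 ± 9.47 against 96.1 ± 18.2 CPM), the alanine transaminase gene Gpt2 (-1.57 ± 0.25), Pycr1 (8.61 ± 1.60 against 19 ± 2.42 CPM) and the mitochondrial enzyme gene Pck2 (52.6 ± 6.27 against 94.6 ± 14.6 CPM) fell. In all, 277 genes changed, 153 higher and 124 lower, 104 of them 2-fold or more.

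Among called genes without overlap of the groups, the largest rises at day 3.5 were in Cdh1 (2.88 ± 0.52), Tnfsf14, a TNF-family ligand (2.35 ± 0.57), Alox5ap, of leukotriene synthesis (2.34 ± 0.30, adjusted p = 0.00097), and the neurotrophin receptor gene Ngfr (2.34 ± 0.40). Gramd2 (9.75 ± 0.505 against 2.15 ± 1.24 CPM), Tspoap1 (2.16 ± 0.41, 93.8 ± 16.2 against 21.1 ± 5.28 CPM), the neonatal Fc receptor gene Fcgrt (7.94 ± 3.11 against 1.80 ± 0.514 CPM) and the quinone reductase gene Nqo1 (12.9 ± 1.07 against 3.62 ± 1.08 CPM) followed. The largest falls by this ranking were in Ifi213 (-2.77 ± 0.53), Aldh1l2, of mitochondrial folate metabolism (-2.67 ± 0.55), Elof1 (-2.23 ± 0.46), Ifi206 (-2.15 ± 0.30) and Usp18. Bicd1 (1.02 ± 0.344 against 4.13 ± 0.646 CPM), P2rx3 (2.41 ± 0.655 against 9.67 ± 2.95 CPM) and Fggy (1.19 ± 0.523 against 3.67 ± 0.477 CPM) came after them. Ighg1 was 1044 ± 128 CPM in cKO and 2610 ± 607 CPM in WT libraries (-1.32 ± 0.17, adjusted p = 0.00097). Ighm was 10463 ± 1567 against 10397 ± 4214 CPM, and Ighe had a log2 fold change of -0.76 (adjusted p = 0.530).

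Other lists at day 3.5 held fewer calls. Of 29 activation genes Cd40 (0.73 ± 0.10, 163 ± 10 against 98.3 ± 10.3 CPM) and Cd86 (0.84 ± 0.17) rose, and Cd44 (599 ± 23.9 against 885 ± 30.7 CPM) and Irf4 (-0.55 ± 0.13) fell. Ski (0.79 ± 0.12), of the 17 TGF-beta response genes, rose, and Egr2 (-0.89 ± 0.21) fell. Of 24 plasma cell genes 2 fell, or 8 adjusted over the list alone (median -0.24, camera adjusted p = 0.000173, adjusted p = 0.513 with an estimated correlation). The 45 S phase genes had a median of 0.15 with none called (camera adjusted p = 0.00204, adjusted p = 0.513 with an estimated correlation), which was -0.14 with fly scaling. Lck (14.7 ± 0.484 against 24.1 ± 4.40 CPM) and Zbtb46 (14.5 ± 2.24 against 24.6 ± 2.28 CPM) fell again. Fly scaling gave 105 calls, 17 higher and 88 lower, and leaving out cKO replicate 3, WT replicate 1, WT replicate 3, cKO replicate 1 or cKO replicate 2 gave 62, 69, 100, 152 and 161. There were 87 without the term for library series and 17 without male mice. The counts were 512 without the filter, 573 by DESeq2 and 864 with only the compared groups in the fit.

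The changes at days 2.5 and 3.5 went the same way. Of the 153 genes higher at day 3.5, 80.4% were among the 377 higher at day 2.5, where 4.32 shared genes were expected of independent lists (Fisher's exact p = 2.55e-169). Of the 124 lower, 90 (72.6%) were among the 316 lower at day 2.5, where 2.93 were expected (Fisher's exact p = 8.53e-123). Of the day 2.5 calls 374 of 377 and 312 of 316 had the same sign at day 3.5. The days share no libraries. Whether they share mice is not given in the sources used here, but the male libraries were replicate 2 of the WT and replicate 3 of the cKO at both days. Both comparisons also come from 1 fit, with a shared estimate of spread and term for library series. These Fisher p-values are therefore not independent evidence. No gene passed a test of a difference between the genotype effects of the 2 days by edgeR or by DESeq2. By edgeR 278 of 13367 had an unadjusted p under 0.05, fewer than the 1 in 20 that chance gives. With the replicate number as a block across the days edgeR called 2 genes, the protease inhibitor gene Slpi (1.47 ± 0.17) and Mir7678 (1.57 ± 0.19), named after their values were seen, with 825 at an unadjusted p under 0.05. Among the smallest p-values of the main fit, without the block, the deubiquitinase gene Mindy3 had a difference of 0.55, the actin-binding peptide gene Tmsb10 one of -0.81 and Iglc2 one of -0.65.

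In wild-type spleen cells 9 of 24 plasma cell genes and 12 of 31 p53 targets rose from day 2.5 to day 3.5, and 8 of 48 genes of G2 and mitosis fell. No list kept its call with an estimated correlation (adjusted p = 0.0642, 0.0623 and 0.0623 for these). Cd28, a receptor of T cells also used by plasma cells, rose from 1.30 ± 0.226 to 13.9 ± 1.15 CPM (3.68 ± 0.31, adjusted p = 3.8e-05), and Jchain, the joining chain of secreted IgM and IgA, from 83.9 ± 22.3 to 332 ± 170 CPM (2.18 ± 0.38). Cdkn1a, the cell cycle inhibitor p21, rose from 18 ± 4.43 to 71.3 ± 22.3 CPM (2.12 ± 0.23, adjusted p = 0.00018), and Zmat3, another p53 target, from 50.8 ± 5.79 to 121 ± 24 CPM. Hist1h1a, a linker histone gene, fell from 602 ± 56.9 to 385 ± 2.06 CPM (-0.65 ± 0.09) and the mitotic kinase gene Plk1 from 171 ± 29.1 to 139 ± 14.6 CPM. Among markers of other cells, the 9 T and NK cell markers had a median of 0.60 with Cd28 called, or 2 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0562). The 7 myeloid markers had a median of 0.26, with Csf3r (2.46 ± 0.46) and Zbtb46 (1.02 ± 0.17) higher (camera adjusted p = 0.103), and of 4 red cell and megakaryocyte markers Car2 fell (-1.23 ± 0.26). In all 729 genes changed, 558 higher and 171 lower, or 2103 with the replicate number as a block across the days, 1202 higher and 901 lower. Leaving out day 2.5 replicate 1 or 3 gave 447 and 373, and leaving out day 3.5 replicate 1, 2 or 3 gave 386, 301 and 333.

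By list, none of the p53 targets fell, and 18 rose adjusted over the list alone, with a median of 0.59 (camera adjusted p = 3.23e-14, adjusted p = 0.0623 with an estimated correlation, fry adjusted p = 0.00155). Sesn2 (62.1 ± 17.7 to 128 ± 20.9 CPM), Psrc1 (30.1 ± 3.79 to 61.6 ± 13.6 CPM) and the death receptor gene Fas (15.4 ± 4.33 to 21.5 ± 2.42 CPM) were other risers. Of the plasma cell genes 16 rose adjusted over the list alone, with a median of 0.54 (camera adjusted p = 1.18e-13, adjusted p = 0.0642 with an estimated correlation, fry adjusted p = 0.00160). Of the genes of G2 and mitosis 21 fell adjusted over the list alone, with a median of -0.25 (adjusted p = 0.0623 with an estimated correlation, fry adjusted p = 0.000829), and of 45 S phase genes 5 fell, among them Pold1 and Mcm2 (adjusted p = 0.0726 with an estimated correlation). Of 60 replication-dependent histone genes 14 fell, with a median of -0.49 (adjusted p = 0.174 with an estimated correlation). Of 11 immunoglobulin constant regions 5 rose, with a median of 0.88 (adjusted p = 0.127 with an estimated correlation), among them Ighg1 (0.88 ± 0.16) and Iglc2 (77.1 ± 6.65 to 153 ± 21.5 CPM). Among called genes without overlap of the days, the largest other rises were in Nol4l, the AP-1 gene Fosl2 (2.51 ± 0.22), the dynein gene Dnah12 and the Notch ligand gene Jag2 (3.85 ± 1.93 to 12.7 ± 1.21 CPM), and the largest falls in Ngfr, Cdh17, the calcium channel gene Cacna1i, the fatty acid receptor gene Ffar2 and Cd38 (18 ± 2.33 to 8.26 ± 2.87 CPM). With fly scaling 167 genes changed, 145 higher and 22 lower, and within the second library series alone, 3 against 3 libraries, 2005 did. There were 421 without the term for library series and 115 without male mice.

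CH12F3 cells at day 1.5 and spleen cells at day 2.5 shared some changes and differed in others. Of 12258 genes tested in both, 10 rose in both, where 2.27 were expected of independent lists (Fisher's exact p = 8.6e-05). In both systems 7 fell, where 1.19 were expected (Fisher's exact p = 0.000168), but these include Elof1, which was lowered by design. The inhibitory ligand gene Cd274 (0.92 in CH12F3, 0.76 in spleen cells), Fgd2 (0.84 and 0.90), the lysosomal genes Ifi30 (0.63 and 0.75) and Psap (0.33 and 0.36), and the small nucleolar RNA host gene Snhg15 (0.80 and 0.67) rose. Besides Elof1, Uqcc2 (chromosome 17, 27122663 to 27133916, minus strand, mm10; -0.69 ± 0.12 and -0.81 ± 0.09), the mitochondrial ribosomal protein gene Mrps28 (-0.67 and -0.57), Arhgef12 (-0.51 and -0.49) and Rasal2 (-1.02 and -0.93) fell. Of the genes higher in CH12F3 cells 9 were lower in spleen cells, Ighg1, Irf4 and Ccl22 among them, where 1.91 were expected (Fisher's exact p = 0.000119). Shared and opposite calls of these genes were thus both above the number expected, so the 10 shared rises alone do not show a like effect. Of the genes lower in CH12F3 cells 3 were higher in spleen cells, where 1.41 were expected (Fisher's exact p = 0.168). Across all genes the fold changes of both systems had a Pearson r of 0.16 and a Spearman rho of 0.23 (permutation p = 1e-05 for each, the smallest that 100000 permutations give), and 59.0% had the same sign. Genes are not independent replicates.

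The ratio of switched isotype to Ighm counts was compared in each library. In spleen cells at day 2.5 the log2 ratio of Ighg1 to Ighm was -3.83 ± 0.26 in cKO and -2.12 ± 0.29 in WT libraries (SD, n = 5 each), a difference of -1.72 with no overlap (2-sided exact permutation p = 0.0079, the smallest the design gives, adjusted p = 0.0595 over 15 tests). Within same-numbered pairs the exact p was 0.0625, the smallest that 5 pairs give. The difference was -1.72 within each library series. At day 3.5 it was -1.38, again with no overlap (exact p = 0.1, the smallest the design gives). In CH12F3 cells the log2 ratio of Igha to Ighm differed by 0.08 at day 1.5 (exact p = 0.83), with 0.42 in the first and -0.27 in the second library series. This day 1.5 difference was 0.33 without ELOF1 replicate 4 (exact p = 0.0286) and -0.065 without ELOF1 replicate 1. At day 3 it was -0.68 ± 0.15 in vector and 0.31 ± 0.94 in ELOF1 libraries, and at day 7 -0.11 ± 0.48 against 1.88 ± 1.37 (SD, n = 2 each). These differences of -0.99 and -1.99 showed no overlap (exact p = 0.333, the smallest the design gives). Without ELOF1 replicate 2 they were -0.32 and -1.02, and without ELOF1 replicate 1 that of day 3 was -1.65. The Igha and Ighg1 counts join germline and switched transcripts, which gene-level counts do not tell apart.

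**Figure D4:**
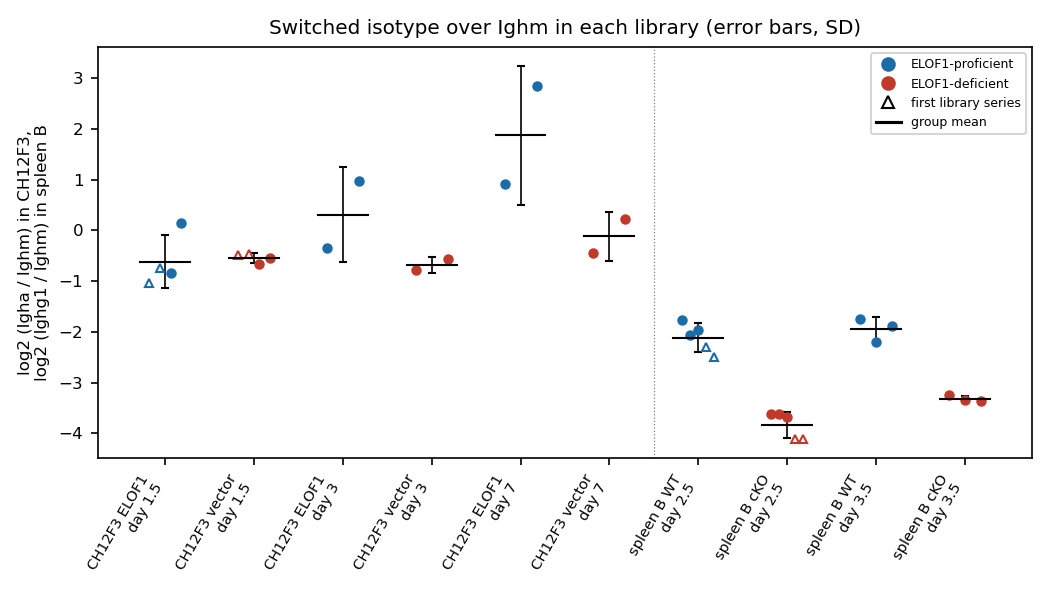
Log2 ratio of Igha to Ighm counts in CH12F3 libraries and of Ighg1 to Ighm counts in spleen libraries, by group, with group means as lines, SD as error bars and open triangles for the first library series. In spleen cells all cKO libraries lie below all WT libraries at both days, with means of -3.83 against -2.12 at day 2.5, and in CH12F3 cells the groups overlap at day 1.5.

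The level of long genes was compared with that of short genes, since elongation factors act along the gene body. Over 1282 genes spanning 100 kb or more and 4738 under 10 kb, the median log2 CPM of long minus short genes was 1.45 ± 0.14 in cKO and 1.68 ± 0.08 in WT spleen libraries at day 2.5 (SD, n = 5 each). The difference of -0.23 showed no overlap of libraries (2-sided exact permutation p = 0.0079, the smallest the design gives, adjusted p = 0.0595). Taken within same-numbered pairs, the exact p was 0.0625, again the smallest that 5 pairs give. The difference was -0.28 in the first and -0.19 in the second library series. At day 3.5 it was -0.14 (exact p = 0.1, the smallest the design gives). In CH12F3 cells, with 1273 long and 5233 short genes, it was -0.09 at day 1.5 (exact p = 0.143), -0.06 at day 3 and -0.11 at day 7 (exact p = 0.667 for each). Leaving out vector replicate 1 turned it to 0.064 at day 3 and 0.044 at day 7, and leaving out ELOF1 replicate 2 turned it to 0.016 at day 3. By span, the median fold change of genes of 100 kb or more was -0.08, -0.08 and -0.10 in CH12F3 cells and -0.13 and -0.14 in spleen cells, against 0.03, 0.00, 0.05, 0.06 and 0.04 for genes under 10 kb. For genes with a mean log2 CPM of 3 or more the day 2.5 difference was -0.13 (exact p = 0.444). With spans of 50 kb or more against under 20 kb it was -0.12 (exact p = 0.111).

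**Figure D5:**
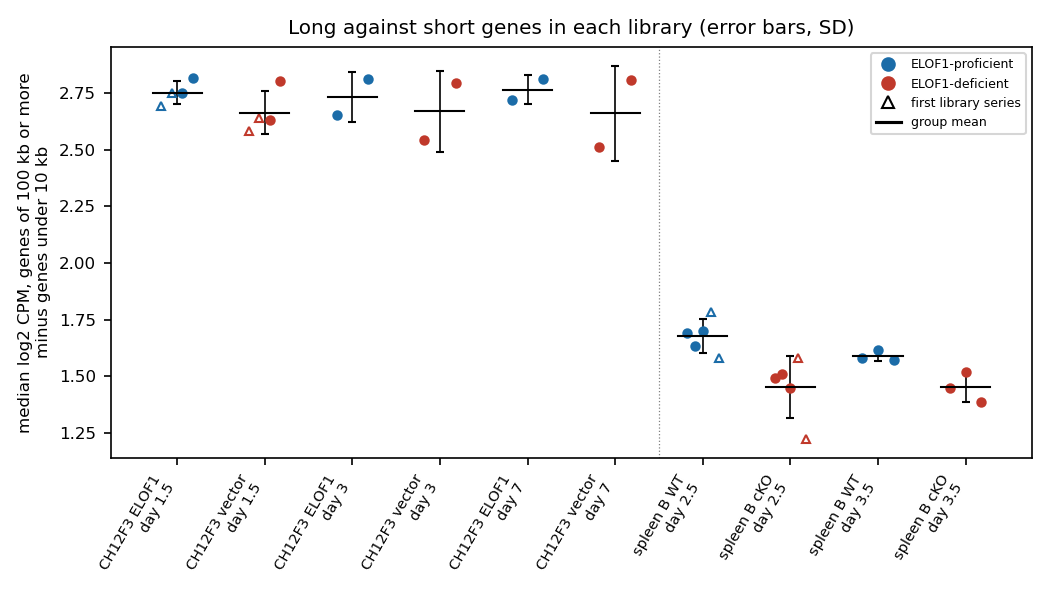
Median log2 CPM of genes spanning 100 kb or more minus that of genes under 10 kb in each library, by group, with group means as lines, SD as error bars and open triangles for the first library series. In spleen cells the cKO libraries lie below the WT libraries at both days, with means of 1.45 against 1.68 at day 2.5, while in CH12F3 cells the groups overlap.

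The fly RNA added per cell gave no call on the amount of mouse RNA. The log2 ratio of fly to mouse counts was higher in deficient cells by 0.07, 0.14 and 0.12 in CH12F3 cells (exact p = 0.714, 0.667 and 0.333) and by 0.11 and 0.25 in spleen cells (exact p = 0.635 and 0.4). In the first and second library series this ratio differed by -0.03 and 0.17 at CH12F3 day 1.5 and by 0.16 and 0.07 at spleen day 2.5. Its SD within a group was up to 0.37, so differences of this size were not detectable between unpaired groups. By replicate number, the deficient library was higher in every pair at spleen day 2.5 and in every CH12F3 pair of the second library series. It was lower in replicate 2 at CH12F3 day 1.5 and at spleen day 3.5. A small difference in the amount of mouse RNA is therefore not excluded. Scaling by fly counts moved the median log2 fold change of all genes to -0.08, -0.19 and -0.14 in CH12F3 cells and to -0.14 and -0.29 in spleen cells.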

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

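For the long genes, the test of genes of low level was chosen only after the result was seen, as were the comparisons of a pattern between both cell systems, the sum of the markers of other cells, the exact tests of list means within same-numbered pairs and the splits for the difference of effects between the spleen days.

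Interferon-stimulated genes were lower in cKO than in WT spleen B cells. At day 2.5 the difference of the list mean was -0.37 (exact p = 0.0159, n = 5 each), with -0.19 in the first and -0.49 in the second library series. The exact p within same-numbered pairs was 0.0625, the smallest that 5 pairs give. At day 3.5 the difference was -0.75 (exact p = 0.1, the smallest the design gives, n = 3 each). This list had stood out in these same libraries, and neither these p-values nor the splits account for that choice. Against the sex of the mice, the day 3.5 difference was -0.82 without the libraries of male mice (2 against 2 libraries), and against a single library, the smallest difference with 1 library left out was -0.64. Fewer T, myeloid or red cells in the cKO cultures stay open, since the sum of their 20 tested markers, 927 CPM in cKO and 847 CPM in WT libraries (a fall of -22.5% of that of the list from 2061 to 1703 CPM), lay to 90.1% in Thy1, Tfrc and Ctss, while Lck and Zbtb46 fell. Of 100 splits drawn at day 2.5, 6 gave a difference as large as the real one (0.38 in size, highest other 0.68), and at day 3.5 the 10 splits are too few (0.80, highest other 0.62). A weaker interferon response of ELOF1-deficient B cells is a hypothesis that no value here tests, and a difference in litter, housing or strain background of the mice, also not tested, may equally account for the pattern.

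Genes of B cell activation and of the IL-4 response, 41 in all, were higher in vector than in ELOF1 libraries of CH12F3 cells at day 1.5, with a difference of the list mean of 0.48 (exact p = 0.0286, or 0.125 within same-numbered pairs, the smallest each can give, n = 4 each). Both lists had stood out among all lists in these same libraries, and neither these p-values nor the splits account for that choice. The difference was 0.65 in the first and 0.31 in the second library series, and 1 of 34 splits gave a mean as large (0.49, highest other 0.44). In spleen cells at day 2.5 the difference was -0.053 (exact p = 0.508, n = 5 each, 39 genes). It lay below a rise of 0.24, or 0.5 times that in CH12F3 cells (exact p = 0.0238, or 0.0625 within pairs, the smallest they give). The CH12F3 value is that of lists picked in its own data, so this argues only against a rise of that size in the list mean of spleen cells, whose stimulus differed. Members went both ways there, with Irf4, Ccl22 and Cd44 lower and Cd86, Cd40 and Il4i1 higher, and the median was -0.06 for the activation list and 0.08 for that of IL-4 and STAT6, or -0.21 and -0.063 with fly scaling. A stronger response to the stimulus without ELOF1 is a hypothesis for CH12F3 cells alone, and the level of the construct, which lay far above that of Elof1 in spleen cells, may also have a part in it and was not tested.

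Genes spanning 100 kb or more were lower against genes under 10 kb in cKO spleen libraries at day 2.5, by -0.23. Taken within 5 bins of exonic length the difference was -0.22, and without ribosomal protein, histone and oxidative phosphorylation genes it was -0.25 (exact p = 0.00794 for each, n = 5 each), each time with all cKO libraries below all WT libraries. These values argue against exonic length and the abundant short families as the whole cause. Over the 3280 genes with a mean log2 CPM of 3 or more the difference was -0.13 with overlapping groups (exact p = 0.444), and in CH12F3 cells at day 1.5 it was -0.088 (exact p = 0.143, or 0.743 against a fall of 0.5 times the spleen value, n = 4 each), so a part of genes of low level and an effect of ELOF1 loss in either system stay open. With spans of 50 kb or more against under 20 kb the spleen difference was -0.12 (exact p = 0.111), so its size depends on the spans chosen. Slower or less complete elongation through long genes is a hypothesis that may be consistent with the spleen values, but these counts do not measure elongation.

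Other splits of the libraries were fitted in the same way. At CH12F3 day 1.5, 1 of the 34 splits that could be fitted gave as many genes, the real one with 164 (highest other 1). These splits leave the pairs out of account, so their share does not exclude chance. Among the 7 other splits that part all 4 pairs the highest count was 0, or 1 with the block, and these are too few for a share under 1 in 20. For the gene lists there, 10 of 34 splits gave as many as the 11 observed (median of the others 9, highest other 14), so chance was not excluded. At spleen day 2.5, 4 of 100 splits drawn of 126 gave as many genes as the 693 observed. The other 3 called 1208, 1051 and 844 genes, and each put both libraries of replicate 4 against both of replicate 5 in the first library series, which points to a structure of these samples. The 13 other splits drawn that part all 5 same-numbered pairs called 0 genes, but these are too few for a share under 1 in 20. The real split gave 855 within the second library series and 1543 with the block, and other splits were not fitted in these ways. The share of 4 in 100 leaves the pairs of the first series out of account, so chance was not excluded for these genes. For the lists there, 80 of 100 splits gave as many as the 5 observed (median of the others 7, highest other 16), so chance was not excluded. At spleen day 3.5 the 10 splits are too few for a share under 1 in 20. As many were given by 1 split for genes (277, highest other 0), by 3 for lists (11, median of the others 8, highest other 16), and by 10 for the difference between the days' effects (0, highest other 1). For WT day 3.5 over day 2.5, 1 of 56 splits gave as many genes (729, highest other 0). These splits leave the pairs across the days out of account, and exchanges within 3 pairs are too few for a share under 1 in 20. Chance was therefore not excluded for these genes. For lists 16 splits gave as many (12, median of the others 10, highest other 16), so chance was not excluded.

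In 14 sets of values, each of 1 gene or measure in a group of 4 or 5 libraries, 1 library stood apart from the rest by Dixon's criterion, where chance, at 1 in 20 of the sets tested, gives 10.7. In CH12F3 cells at day 1.5, Mir7676-1 was at 2.58 log2 CPM in ELOF1 replicate 4 (1.55 to 1.69 in the others), mitochondrial mRNA made up 0.471% of counts in vector replicate 2 (1.04% to 1.16%), and Trp53bp1 was at 7.45 there (7.12 to 7.16). Of the 11 in spleen cells at day 2.5, 9 lay in replicates 4 and 5, the libraries of the first series. In WT replicate 4 S1pr1 was at 2.82 (3.64 to 3.94) and Zbtb20 at 7.86 (5.92 to 6.24). In cKO replicate 4 Ebf1 was at 6.71 (6.15 to 6.29), S1pr1 at 3.74 (4.52 to 4.71) and Zbtb20 at 6.03 (4.16 to 4.68). In replicate 5, Ccr7 was at 3.81 (4.73 to 4.94) and Slbp at 6.95 (6.40 to 6.48) in the WT, and Elof1 was at 0.52 (2.06 to 2.58) and Klf2 at 6.40 (7.67 to 7.93) in the cKO. Gramd2 at 1.84 (2.18 to 2.28) and Ighm at 12.76 (12.19 to 12.32) stood apart in WT replicate 2.

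Within each day, Ighg1 was higher in each vector than in each ELOF1 library of CH12F3 cells and lower in each cKO than in each WT library of spleen cells. Its log2 fold change was 1.54 at CH12F3 day 1.5 and -1.43 at spleen day 2.5, a difference of 2.96 that was not tested itself.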

How the results depend on the processing

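The runs without libraries of male mice, the block for the differences in effect between CH12F3 days, the gene lists within a library series, permutation within a library series and permutation of list means within pairs were tests chosen only after the data were seen, and all other alternatives were planned before the data were examined. Unless a reason is given, the cause was not tested.

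Of the values of named genes under the alternatives, 3134 stayed on their side of the threshold, 923 no longer passed it, 32 newly passed it, and 39, all of genes that were not called, turned in sign, while no called value turned. DESeq2 size factors within edgeR moved no count of calls by more than 1.5 times. Without the filter 24142 CH12F3 and 23188 spleen genes were tested, and whether depth limits the calls of low genes was not tested.

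The counts of calls moved more. At CH12F3 day 1.5 (164) they were 45 with fly scaling, 735 without the filter, 22 without the term for library series, 64 with only the compared groups in the fit, 52 and 0 in the first and second series alone (edgeR, 902 at an unadjusted p under 0.05 in the second) and 447 by DESeq2. The series runs hold 2 against 2 libraries. At CH12F3 day 3 (1) they were 48 without the filter, 0 with only the compared groups (edgeR, 441 at an unadjusted p under 0.05) and 13 by DESeq2. At CH12F3 day 7 (5) they were 1 with fly scaling, 110 without the filter, 1 without the series term, 8 with robust dispersions, 0 with only the compared groups (502 at an unadjusted p under 0.05) and 27 by DESeq2. For ELOF1 cells at day 3 over day 1.5 (1) they were 64 without the filter, 0 with fly scaling, without the series term and in the second series alone (in the latter pair 659 and 644 at an unadjusted p under 0.05 by edgeR), and 23 by DESeq2. At day 7 over day 1.5 (7) they were 4 with fly scaling, all higher, 2.3e+02 without the filter (101 higher and 125 lower), 0 without the series term and in the second series alone (1563 and 1061 at an unadjusted p under 0.05), and 101 by DESeq2. Without the filter 3 and 18 genes differed in effect between CH12F3 day 1.5 and days 3 and 7.

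At spleen day 2.5 (693) the counts were 93 with fly scaling, 203 without the series term, 343 with only the compared groups, 0 in the first series alone (195 at an unadjusted p under 0.05) and 173 without male mice. At spleen day 3.5 (277) they were 105 with fly scaling, 512 without the filter, 87 without the series term, 864 with only the compared groups, 573 by DESeq2 and 17 without male mice, which leaves 2 against 2 libraries. For WT day 3.5 over day 2.5 (729) they were 167 with fly scaling, 421 without the series term, 2005 in the second series alone and 115 without male mice. Without the filter 16 genes differed in effect between the spleen days.

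With the replicate number as a block, 1221, 35 and 70 genes were called at CH12F3 days 1.5, 3 and 7, and 1543 and 830 at spleen days 2.5 and 3.5. Between genotypes of spleen cells the numbers pair the libraries clearly only within the first series, with a correlation of 0.78, and not every library correlated best with its own number. A block across the spleen days gave 2103 genes for the time step and 2 for the difference in effects, and the block gave 0 for both differences in effect between CH12F3 days (edgeR, 368 and 652 at an unadjusted p under 0.05). The block took the exact p of the isotype ratio at spleen day 2.5 to 0.0625 (-1.72), the smallest that 5 pairs can give, and that of the long minus short level to 0.0625 (-0.23). No other per-library value had an exact p under 0.05 without the block, and pairs this few cannot give one, so no other call could change. For gene lists the block gave 11, 10 and 11 calls in CH12F3 and 7 and 11 in spleen cells.

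Camera with its preset correlation called 11, 11 and 11 gene lists at CH12F3 days 1.5, 3 and 7. With an estimated correlation there were 2, 0 and 0. By fry there were 3, 0 and 1, of which 2, 0 and 0 were among those of the preset correlation. The 10 and 13 of the CH12F3 time steps became 3 and 0, and 5 and 3 by fry. The 5, 11 and 12 of spleen days 2.5 and 3.5 and the WT time step became 0 each with an estimated correlation, and the former pair became 1 and 2 by fry. Within the first series 6 lists were called at CH12F3 day 1.5 and 1 at spleen day 2.5, and within the second 11 at spleen day 2.5.

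Of the per-library values, the long minus short level at spleen day 2.5 was -0.12 (exact p = 0.111) with spans of 50 kb or more against under 20 kb, -0.10 (exact p = 0.468) with exonic length, and -0.13 with a mean log2 CPM of 3 or more. With exonic length it turned to 0.0093 at CH12F3 day 1.5 and 0.059 at CH12F3 day 3. The isotype difference at CH12F3 day 1.5 turned to -0.25 with the log2 CPM of Igha alone.

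With each library left out in turn, CH12F3 day 1.5 gave 41 to 144 genes, moved by over 1.5 times without vector replicate 2 (41), 1 (58) or 4 (98) or ELOF1 replicate 1 (48), 2 (62) or 3 (66). The counts were 0 to 1 at day 3, where leaving out either vector library gave 0, 0 to 2 at day 7 (0 without vector replicate 1, 1 without ELOF1 replicate 1, 2 without either replicate 2), 0 to 1 for day 3 over day 1.5, where only ELOF1 day 1.5 replicate 2 could be left out with the call kept, and 0 to 8 for day 7 over day 1.5, with 0 without ELOF1 day 1.5 replicate 4 or either day 7 library and 4 without ELOF1 day 1.5 replicate 1 or 3. Spleen day 2.5 gave 425 to 801, the lowest without WT replicate 1, with 448 without cKO replicate 2 and 450 without cKO replicate 3. Day 3.5 gave 62 (without cKO replicate 3) to 2.1e+02 (rounded), with 69 and 100 without WT replicates 1 and 3 and 152 and 161 without cKO replicates 1 and 2, and the WT time step gave 301 (without WT day 3.5 replicate 2) to 1045, with 447 and 373 without day 2.5 replicates 1 and 3 and 386 and 333 without day 3.5 replicates 1 and 3. The isotype difference at CH12F3 day 1.5 ran from -0.065 (without ELOF1 replicate 1) to 0.33 (without ELOF1 replicate 4, exact p = 0.0286). The fly to mouse ratio ran from -0.041 (without vector replicate 1, and also below 0 without ELOF1 replicate 4) to 0.20 at CH12F3 day 1.5 and from -0.041 (without WT replicate 5) to 0.21 at spleen day 2.5. The long minus short level ran from -0.19 to 0.064 at CH12F3 day 3 (the highest without vector replicate 1, with 0.02 without ELOF1 replicate 2) and from -0.25 to 0.044 at day 7 (the highest without vector replicate 1). A library left alone in its group is assumed to vary like the others.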

Other observations

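The genes named here outside the rule were chosen after their values were seen, and the sex genes were a test chosen only after the data were seen. From day 2.5 to day 3.5 in wild-type spleen cells, 4 of 27 genes of the integrated stress response rose and none fell, with a median of 0.26 (camera adjusted p = 0.0423, adjusted p = 0.495 with an estimated correlation): Sesn2 (0.88 ± 0.18), which restrains mTORC1, Pycr1 (0.76 ± 0.17), Atf5 (0.80 ± 0.20) and Gpt2 (0.94 ± 0.23). Of 27 immediate-early genes 4 rose, among them the AP-1 gene Fosb (1.85 ± 0.38) and Egr2 (0.87 ± 0.19), and Nfkbiz fell (-0.62 ± 0.14), with a median of 0.24 (camera adjusted p = 0.0108, adjusted p = 0.462 with an estimated correlation). Of 29 activation genes 4 rose, among them Cd44 (0.76 ± 0.11) and Stat5a (0.66 ± 0.13), and the costimulatory ligand gene Icosl (-1.82 ± 0.40) and Batf (-0.52 ± 0.12) fell. Of 34 mature B cell genes the complement receptor gene Cr2 (-0.89 ± 0.23) and the BAFF receptor gene Tnfrsf13c (-0.41 ± 0.10) fell, and Bcl6 (0.81 ± 0.18) and Ccr7 (0.74 ± 0.19) rose. The 80 genes of oxidative phosphorylation had a median of -0.17, 72 of them negative and none called (camera adjusted p = 1.26e-06, adjusted p = 0.412 with an estimated correlation). Of 34 MYC target and ribosome biogenesis genes Ldha (-0.64 ± 0.16) and Bop1 (-0.33 ± 0.09) fell, with a median of -0.26 (camera adjusted p = 3.08e-06, adjusted p = 0.457 with an estimated correlation).

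In ELOF1-proficient CH12F3 cells all 24 cholesterol synthesis genes had positive fold changes from day 1.5 to day 7, with a median of 0.46 and none called (camera adjusted p = 7.19e-15, adjusted p = 0.267 with an estimated correlation). Histone genes had a median of 0.31, with 55 of 58 positive and 2 higher adjusted over the list alone (camera adjusted p = 1.59e-20, adjusted p = 0.222 with an estimated correlation), and 33 of 34 MYC target and ribosome biogenesis genes were positive, with a median of 0.18 (camera adjusted p = 2.76e-08, adjusted p = 0.288 with an estimated correlation). The integrated stress response list had a median of 0.18 in vector over ELOF1 CH12F3 cells at day 1.5, where Sesn2 rose (0.51 ± 0.08) and 6 of 23 genes were higher adjusted over the list alone (camera adjusted p = 5.68e-05, adjusted p = 0.333 with an estimated correlation). Of 20 plasma cell genes there, Ighg1 and Irf4 rose and Prdm1 fell. The cholesterol synthesis list, with a median of 0.40 in vector over ELOF1 cells at day 1.5 (adjusted p = 0.333 with an estimated correlation), had medians of 0.24 and 0.16 at days 3 and 7, and of -0.15 and -0.22 in cKO over WT spleen cells at days 2.5 and 3.5, with none called in any of these. The difference between the systems was not tested for these lists.

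Libraries were arranged by more than their groups. The first principal component held 40.3% of the variance in CH12F3 libraries and 32.7% in spleen libraries and separated the library series in both. The second held 13.8% in CH12F3 cells and separated replicate 3 of day 1.5 and replicate 1 of days 3 and 7, in both genotypes, from replicate 4 of day 1.5 and replicate 2 of days 3 and 7. In spleen cells it held 18.2% and separated replicate 4 from replicate 5. Xist counts were 3 to 11 in the 4 spleen libraries with 555 to 785 counts of Ddx3y, and 4791 to 15211 in the other 12, with 0 to 3 counts of Ddx3y.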
